A study of Mus musculus with 9 samples.

How the data were processed

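The series measured messenger RNA in macrophages from the peritoneal cavity of male C57BL/6 mice of 6 weeks of age on 9 single-colour Affymetrix expression arrays. Per the labels, total RNA was extracted with TriZol and labelled with biotin by an Affymetrix whole-transcript terminal labelling kit. The submitters' processing notes name Affymetrix Power Tools and RMA (robust multi-array average, which corrects background, normalizes and summarises the probes of each probe set), with no version. They do not state which arrays were normalized together. The deposited values are RMA intensity on a linear scale, 1 value per probe set and array. The quartiles of the 9 deposited columns differ, so these columns do not share 1 distribution. Arrays give no count of molecules, and their number limits the precision.

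The log2 of each deposited intensity was taken. The deposited table held 24922 probe sets, of which 21425 carried exactly 1 gene symbol in the platform table, 1399 carried several, and 2098 carried none or were not listed there. Each gene was represented by the probe set with exactly 1 symbol and the highest mean over the 9 arrays, which left 19752 genes. For 921 of these genes more than 1 probe set was available. The Entrez identifiers of 19677 genes were found in the mouse reference annotation, which was used for names only. Genes without a probe set of their own were not analysed here. No filter on low intensity was applied.

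Samples were grouped by the treatment label into untreated (n = 3), IFNa (n = 4) and IFNg (n = 2). A linear model with 3 group means was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (6 residual and 3.62 prior degrees of freedom). The spread within groups was therefore shared between the groups, and the 2 IFNg arrays were assumed to vary like the others. The comparisons were IFNa against untreated, IFNg against untreated and IFNa against IFNg. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called changed at an adjusted p under 0.05. Errors given after a log2 change are standard errors from this model. Tested on simulated data with 200 changed genes, the model recovered 89.0%, 66.0% and 70.0% of 2-fold changes in the 3 comparisons in the order given. Of the genes it called in these simulations, 10 of 197, 21 of 184 and 2 of 171 were not among those changed. The share of false calls lay above the threshold in the first 2 comparisons, most for IFNg against untreated. Each comparison had a single simulated data set, in which genes varied independently, so these shares do not measure the error rate in the real arrays.

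Gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The 27 lists held 543 entries, of which 475 matched a gene with a value. They covered antiviral interferon-stimulated genes, interferon-inducible GTPases, IFN-gamma-associated genes, MHC class I and processing, MHC class II, interferon receptor signalling, feedback inhibitors, nucleic-acid sensing and Toll-like receptors, chemokines, inflammatory NF-kB targets, cell death, Schlafen and TRIM genes, complement, alternative activation, cholesterol synthesis and cell cycle. Cell type lists covered large peritoneal macrophages, small peritoneal macrophages with monocytes and dendritic cells, B cells, T and NK cells, mast cells, neutrophils and eosinophils, mesothelial and stromal cells, and erythroid cells and platelets. Handling lists covered immediate early, heat shock and glucocorticoid target genes. Each list was tested against all other genes with camera from limma at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Adjustment was over the 81 list tests.

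Named genes were, for each comparison with untreated, the 15 largest rises and 8 largest falls among called genes whose treated arrays all lay beyond all untreated arrays. In the direct comparison they were the 10 largest differences each way among called genes whose arrays did not overlap between the groups. Predicted genes and receptor families of smell were not named from this part. Up to 4 members of each list with the smallest p, and 15 genes fixed in advance, completed the rule. Of those 15 genes, 12 had a probe set of their own.

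Alternatives fixed before the data were examined were an intensity trend in the variances, robust variances, removal of the dimmest 30% or 50% of genes, quantile normalization between arrays, median centring, a fit of only the groups compared, array weights and blocks by the replicate numbers of the titles or descriptions. Further ones kept every probe set, required at least a 2-fold change or an adjusted p under 0.01, or left out each array in turn. A fit without the 2 arrays of narrow intensity range and a fit with the range as a covariate were added after seeing the data. Other tools were Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.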

Results

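Gene expression was measured in peritoneal macrophages 2 h after a single subcutaneous injection of interferon into mice. Mice received 10000 U of recombinant interferon alpha (IFNa, a type I interferon, n = 4), 8000 U of recombinant interferon gamma (IFNg, the type II interferon, n = 2) or no treatment (n = 3). No mice injected with vehicle alone were included, so differences from untreated, higher or lower, may include effects of injection or handling. Cells from the peritoneal lavage were sorted by flow cytometry in 2 rounds. The label of the treated samples gives F4/80 and ICAM2, markers of the resident large peritoneal macrophage, and that of the untreated samples gives F4/80 alone, whereas the description of the series gives F4/80 and ICAM for all cells. Adgre1, which encodes F4/80, differed from untreated by log2 0.04 ± 0.10 after IFNa and 0.01 ± 0.12 after IFNg. Icam2 differed by -0.24 ± 0.14 and 0.05 ± 0.17, and neither gene passed the test.

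Median intensity ranged from 162.2 to 178.3 over the 9 arrays. The ratio of the upper to the lower quartile was narrowest in IFNa replicate 4, at log2 2.16, and in untreated replicate 1, at 2.27. In the other arrays it ranged from 2.68 to 3.03. IFNa replicate 4 also had the lowest mean correlation with the other arrays across genes, 0.947, against 0.963 for untreated replicate 1 and 0.976 to 0.980 for the rest. The total counts of genes below are therefore also given without these 2 arrays, an alternative chosen after seeing the data, as are the counts within lists that moved by over 1.5 times.

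The first comparison asked which genes respond to IFNa. The largest rises included those of genes that restrict viral replication. Ifit3, Ifit1 and Ifit2, whose products bind foreign RNA or act with those that do, rose by log2 6.39 ± 0.19 (84.1-fold), 6.12 ± 0.25 (69.4-fold) and 5.60 ± 0.16 (48.5-fold) in 4 IFNa against 3 untreated mice. Rsad2, which encodes the antiviral enzyme viperin, rose by 5.68 ± 0.23, and the antiviral GTPase genes Mx1 and Mx2 rose by 5.14 ± 0.25 and 4.98 ± 0.24. Cxcl10, a chemokine that attracts activated T cells, rose by 5.47 ± 0.21 (44.2-fold). Usp18, a protease that removes ISG15 and dampens type I signalling, rose by 4.67 ± 0.27. Adjusted p-values of these genes lay between 2.45e-07 and 1.10e-05. Each was higher in 4 of 4 IFNa arrays than in any untreated array, which the naming rule required. Further large rises were those of BC023105 (5.37), Ifi213 (5.23), Iigp1 (5.22), Ifi205 (5.02), Ifit3b (4.95), Ifi208 (4.66) and Cmpk2 (4.65). The untreated levels of BC023105 and Ifit3b, intensities of 25.7 and 20.3, lay near or below the 5th percentile of the untreated arrays (24.1 to 27.9), so the sizes of their changes are not exact.

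Of 34 antiviral genes measured, 33 rose after IFNa, with a list median of log2 2.74. The exception was Ifitm3 (0.12, adjusted p = 0.826), singled out after its values were seen. Some of the listed interferon-inducible GTPases, such as Gbp2, had no probe set of their own. All 10 GTPases measured rose, among them Gbp5 (3.72) and Irgm1 (3.71), which act against intracellular pathogens. So did 14 of 17 Schlafen and TRIM genes, including Slfn5 (3.47) and Trim21 (1.96). Of 17 MHC class I and processing genes, 4 rose: H2-T24 (2.52), the peptide transporter gene Tap1 (1.74), Psmb9 (0.91) and Psme2 (0.88). These 4 lists passed the list test with a preset correlation and with an estimated one (adjusted p = 0.0241, 0.0186, 0.0249 and 0.0457). Adjusted over the list alone, 33, 10, 17 and 7 of their members rose. The calls of Psmb9 and Psme2 ended without untreated replicate 2 (adjusted p = 0.0838 for Psmb9, 0.0535 or more for Psme2), and that of Psme2 also without IFNa replicate 1.

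Other immune lists moved in part. Of 24 IFN-gamma-associated genes, 11 rose after IFNa, such as Cd274 (3.40), which encodes the inhibitory ligand PD-L1, Fcgr1 (2.75) and the transcription factor gene Irf1 (2.39). The list passed at the preset correlation but not with an estimated one (adjusted p = 0.0511 with an estimated correlation). The same held for 10 of 26 genes of nucleic-acid sensing, such as Ifih1 (2.44) and Tlr3 (2.07), sensors of double-stranded RNA (adjusted p = 0.103 with an estimated correlation), of which 9 rose under median centring and 13 under quantile normalization. It held for 8 of 19 cell death genes, such as the death ligand gene Tnfsf10 (3.72) and Zbp1 (2.76), with adjusted p = 0.0731 with an estimated correlation. The feedback inhibitors Usp18, Socs2 (2.64), Socs1 (2.00) and Trim21 rose of 11 measured (adjusted p = 0.127 with an estimated correlation). A 2nd probe set for Socs2 gave 0.79. The chemokine genes Cxcl10, Ccl2 (2.93), Ccl7 (2.86) and Ccl12 (1.94), the last 3 of which attract monocytes, rose of 20 (adjusted p = 0.415 with an estimated correlation). Their list had a median of -0.01 and a mean of 0.59, so its test and median differed in sign, and median centring turned the median to 0.02. Stat2 (3.07), a mediator of the type I signal, and Jak2 (1.10) rose of 13 receptor signalling genes (adjusted p = 0.629 with an estimated correlation), and the list median of 0.10 turned to -0.04 under quantile normalization. Jak2 did not pass without untreated replicate 2, IFNa replicates 1, 2 or 3 or either IFNg array (adjusted p = 0.0544 to 0.0962), nor under median centring (0.0525). The cytokine gene Il6 (2.31 ± 0.29, adjusted p = 0.0018) rose alone of 26 NF-kB targets, a list that did not pass (adjusted p = 0.302) and whose median of 0.03 turned to -0.01 under quantile normalization.

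Irf7, which amplifies type I interferon production, rose by 3.18 ± 0.28 after IFNa. Cxcl9 (0.27 ± 0.17, adjusted p = 0.661) and Ciita (0.13 ± 0.13, adjusted p = 0.87), the master regulator of MHC class II, did not pass, and no MHC class II gene of 10 did (list median -0.13, adjusted p = 0.426). No gene passed of 13 for alternative activation (median 0.10, adjusted p = 0.469), of 18 for cholesterol synthesis (median -0.18) or of 27 for cell cycle (median 0.44). The cholesterol list passed as lower (adjusted p = 0.0114, and 0.629 with an estimated correlation) and the cell cycle list as higher (2.91e-05, and 0.629 with an estimated correlation). In the complement list 1 gene of 15 rose, Cfb (0.57, adjusted p = 0.05), which passed under neither scaling alternative (list median -0.01, adjusted p = 0.812, and 0.02 under median centring).

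The largest falls after IFNa were smaller than the rises. Sox7, a transcription factor gene, fell by 1.69 ± 0.18 on the log2 scale, Engase, which encodes a deglycosylating enzyme, fell by 1.61 ± 0.19, and the serotonin receptor gene Htr2a fell by 1.53 ± 0.17. S1pr1, a receptor for sphingosine-1-phosphate, fell by 1.43 ± 0.27, and Ptger4, a receptor for prostaglandin E2, fell by 1.37 ± 0.25. P2ry2, Akna and Trib1 followed at -1.35, -1.21 and -1.19. Gata6, the transcription factor gene that maintains large peritoneal macrophages, fell by 1.05 ± 0.17 (2.07-fold, adjusted p = 0.00997) and was the single called gene of 23 in that macrophage list (median -0.11, adjusted p = 0.107). Without untreated replicate 2 the falls of S1pr1, Ptger4, Trib1 and Gata6 no longer passed (adjusted p of Gata6 0.0641, of the others up to 0.117). Without untreated replicate 3 those of S1pr1, Ptger4 and Trib1 did not, nor did S1pr1 without IFNa replicate 1 or 3 (0.0512 or more) or Trib1 without IFNa replicate 3 (0.0636 or more).

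Markers of other cells changed little after IFNa. Plac8 (1.00, adjusted p = 0.0156) was the called gene of 17 in the list of small macrophages, monocytes and dendritic cells, and Klrk1 (1.48), which encodes the activating receptor NKG2D, that of 18 T and NK cell genes. Both genes can be expressed outside these cells. Plac8 did not pass without untreated replicate 2 or IFNa replicate 2 (adjusted p up to 0.0851). No gene passed in the lists for B cells, mast cells, neutrophils and eosinophils, mesothelial and stromal cells, or erythroid cells and platelets, whose medians were 0.11, -0.04, -0.04, 0.01 and 0.01. The 7 cell type lists other than that of the large macrophage had adjusted p of 0.38 or more, and the T and NK list had a median of -0.02, turned to 0.01 by median centring, and a mean of 0.05. Of the immediate early genes Atf3 (1.61) and Gadd45b (0.78, named after its values were seen) rose and Nr4a1 (-0.87), Ier2 (-0.84) and Jund (-0.61) fell, of 23 (median -0.16, adjusted p = 0.0495, and 0.629 with an estimated correlation). The number lower was 6 under quantile normalization and 1 under median centring, the number higher was 1 under both, and without untreated replicate 2 none of the 3 falls passed (adjusted p = 0.0724 for Jund). No heat shock gene of 12 passed (median 0.51, adjusted p = 1.17e-05, and 0.381 with an estimated correlation). Among 16 glucocorticoid targets Fkbp5 (2.33) rose and Per1 (-0.83, adjusted p = 0.049) fell, and the list did not pass (median 0.04, adjusted p = 0.288). Under quantile normalization 2 of these targets were higher and 2 lower, and under median centring Per1 did not pass (0.101) and none was lower. Nr4a1 kept its call only without IFNa replicate 4 or untreated replicate 1, Ier2 without IFNa replicate 3 or 4, Per1 without IFNa replicate 1 or untreated replicate 1, and Cfb, of the complement list, without untreated replicate 3 (adjusted p otherwise 0.0553 to 0.245).

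In all, 354 genes were higher and 169 lower after IFNa, of 19752 tested, and 267 and 26 of these changed at least 2-fold. Without the 2 arrays of narrow range the numbers were 468 and 638, and they included 342 of the 354 and 163 of the 169. Quantile normalization moved the share of called genes that were higher from 67.7% to 54.3% (500 higher and 421 lower), and it called 1 gene lower in each of the lists for receptor signalling, NF-kB targets, cell death, alternative activation and neutrophils. Adjusted over the list alone, the numbers higher and lower were 12 and 0 of the IFN-gamma-associated genes, 14 and 2 for nucleic-acid sensing, 9 and 1 for cell death, 4 and 1 for feedback inhibitors and 3 and 1 each for receptor signalling and NF-kB targets. They were 2 and 6 for immediate early genes, 3 and 2 for glucocorticoid targets, 4 and 0 for heat shock and 0 and 1 for neutrophils. Leaving out both narrow arrays moved the number lower from 3 to 7 for immediate early genes, from 1 to 2 each for glucocorticoid targets and large macrophages, from 0 to 2 each for NF-kB targets and neutrophils, and from 0 to 1 each for receptor signalling, feedback inhibitors, nucleic-acid sensing, cell death and alternative activation. It moved the number higher from 1 to 3 for glucocorticoid targets, from 0 to 1 for cell cycle and from 1 to 0 for complement. List medians in that fit were -0.03 for MHC class II, 0.03 for alternative activation, 0.32 for heat shock, -0.01 for receptor signalling, -0.07 for large macrophages and -0.03 each for NF-kB and glucocorticoid targets. Of the lists past the threshold, leaving out 1 array ended receptor signalling (without untreated replicate 1 or IFNa replicate 2 or 3, adjusted p up to 0.627) and chemokines (untreated replicate 1 or 3, up to 0.0905). It also ended cholesterol synthesis (untreated replicate 3 or IFNa replicate 4, up to 0.638) and immediate early genes (untreated replicate 2 or 3 or IFNa replicate 1, 2 or 4, up to 0.318). The number lower was 27 without untreated replicate 2, 101 without untreated replicate 3 and 255 without untreated replicate 1. It was 68, 94 and 62 without IFNa replicates 1, 2 and 3, and 74 in the fit of only the 2 groups compared. Leaving out either IFNg array gives that same fit here, since the lone array left adds nothing to the shared spread.

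The next comparison asked which genes respond to IFNg. The largest rises included those of GTPase genes whose products attack the vacuoles of intracellular pathogens. Iigp1 rose by log2 5.76 ± 0.28 (54.2-fold) in 2 IFNg against 3 untreated mice, Gbp4 by 4.60 ± 0.33, Gbp11 by 4.46 ± 0.26, Gbp5 by 4.21 ± 0.19 and Irgm1 by 3.92 ± 0.31. Cxcl10 and Cxcl9, chemokine genes whose products attract T cells, rose by 4.79 ± 0.25 (27.7-fold) and 4.34 ± 0.20 (20.3-fold). Acod1, which encodes the enzyme that makes itaconate, rose by 4.18 ± 0.19 (18.1-fold), and Cd274 by 4.13 ± 0.27. Ciita rose by 1.77 ± 0.16 (3.42-fold, adjusted p = 4.75e-04), the single gene of 10 in the MHC class II list to do so (list median -0.16, adjusted p = 0.691). Adjusted p-values of the genes above other than Ciita lay between 6.85e-06 and 2.03e-04. Each was higher in 2 of 2 IFNg arrays than in any untreated array, which the naming rule required. The largest value of all was that of BC023105 (6.30), whose untreated level of 25.7 lay near the 5th percentile of the untreated arrays, so its size and rank are not exact. Ifi205 (3.67), the signalling inhibitor gene Socs1 (3.58), Irf1 (3.50), Gdap10 (3.44) and Batf2 (3.36) completed the 15 largest. A dimmer 2nd probe set for Irf1 gave 1.36 after IFNg and 0.51 after IFNa, against 3.50 and 2.39 for the one used.

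All 10 interferon-inducible GTPases measured rose after IFNg (list median 4.06), as did 18 of 24 IFN-gamma-associated genes (1.90) and 20 of 34 antiviral genes (1.40). Of the antiviral genes, Parp9 (2.58), Zbp1 (2.49), Parp14 (2.24) and Oas2 (1.57) had the smallest p. The number of antiviral genes that rose was 21 under quantile normalization and 16 under median centring. Of 11 feedback inhibitors 4 rose, Socs1, Usp18 (2.40), Socs2 (1.79, and 0.34 at its 2nd probe set) and Trim21 (1.79). Of 19 cell death genes 10 rose, such as Casp12 (2.61) and Tnfsf10 (2.02), and of 17 Schlafen and TRIM genes 7 rose, such as Slfn5 (2.68) and Slfn8 (1.61). The untreated level of Casp12, 29.1, lay just above the 5th percentile of the untreated arrays (24.1 to 27.9), so the size of its rise is not exact. In the MHC class I list Tap1 (2.23), H2-T24 (1.96) and Psmb9 (1.49) rose of 17. Under median centring 8 cell death genes and 6 Schlafen and TRIM genes rose. These 7 lists passed with a preset correlation and with an estimated one (adjusted p = 0.0186 to 0.0496). The feedback inhibitors Socs1, Usp18 and Trim21 each belong to another of these lists as well, so the 7 results are not separate. Adjusted over the list alone, 10, 19, 27, 9, 12, 15 and 12 members rose in the order given, and 1 cell death gene fell. Usp18 and Slfn8 did not pass without IFNg replicate 1 or 2, nor did Socs2, Slfn5 and Psmb9 without IFNg replicate 1 (adjusted p = 0.0638 to 0.0967 over these genes).

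Of 26 genes of nucleic-acid sensing 5 rose after IFNg: Ifi205, Sting1 (2.16), Nod1 (1.82), Ifi203 (1.52) and Tlr3 (1.03), the last named after its values were seen (adjusted p = 0.234 with an estimated correlation). The chemokine genes that rose, of 20, were Cxcl10, Cxcl9, Ccl2 (2.72), Ccl12 (2.11) and Ccl7 (2.86, named after its values were seen). Their list had a median of -0.04 and a mean of 0.76 (adjusted p = 0.304 with an estimated correlation), and median centring turned the median to 0.01. Of 26 NF-kB targets Tnfaip2 (2.62), the adhesion molecule gene Icam1 (2.17) and Sod2 (1.27) rose (median -0.06, mean 0.23, adjusted p = 0.149). Stat2 (2.50) rose alone of 13 receptor signalling genes (median 0.21, adjusted p = 0.629 with an estimated correlation), and without untreated replicate 1 that list did not pass at the preset correlation either (0.102). Il4ra (1.30), the receptor chain for interleukin 4, rose alone of 13 genes of alternative activation (median 0.04, adjusted p = 0.169), and not under quantile normalization, where the median was -0.02. No complement gene of 15 passed (median 0.03, and -0.01 under quantile normalization, adjusted p = 0.288), none of 18 for cholesterol synthesis (median 0.02, and -0.05 under quantile normalization, adjusted p = 0.839) and none of 27 for cell cycle (median 0.78, adjusted p = 3.84e-10, and 0.565 with an estimated correlation). Sting1 and Ccl12 did not pass without IFNg replicate 1 (adjusted p up to 0.211), nor did they or Ccl2 without IFNg replicate 2 (0.105 for Sting1, 0.137 for Ccl2). Sod2 did not pass under median centring (0.0587). Sod2 and Il4ra did not pass without untreated replicate 2 or either IFNg array, nor Sod2 without IFNa replicates 1, 2 or 3 or Il4ra without untreated replicate 1 (adjusted p up to 0.332 and 0.244).

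Of the antiviral genes that led after IFNa, Ifit1 rose by 1.59 ± 0.30 after IFNg (3.01-fold, adjusted p = 0.0333), and Irf7 by 1.81 ± 0.34 (adjusted p = 0.0333). Mx1 stood at 1.47 ± 0.30 (adjusted p = 0.0531) and did not pass. Neither Ifit1 nor Irf7 passed without untreated replicate 2, IFNa replicates 1, 2 or 3, or either IFNg array (adjusted p = 0.0597 to 0.447). Median centring ended both calls (0.0542 and 0.0572), and quantile normalization ended that of Ifit1 (0.0549).

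The largest falls after IFNg were those of S1pr1 (-1.87 ± 0.32), Sox7 (-1.64 ± 0.21), Htr2a (-1.59 ± 0.21) and Gpr183 (-1.57 ± 0.23), an oxysterol receptor that guides immune cells. Engase (-1.38), P2ry2 (-1.36), Fhl3 (-1.26) and Gata6 (-1.16 ± 0.21, adjusted p = 0.0242) followed. Gata6 was again the single called gene of 23 in the large macrophage list, which passed as lower (median -0.09, adjusted p = 0.0495, and 0.565 with an estimated correlation) but not without IFNg replicate 1 or untreated replicate 3 (adjusted p = 0.222 to 0.354). Each of these falls failed to pass without at least 1 IFNg array: all but Sox7 without IFNg replicate 1, and all but Htr2a and Fhl3 without IFNg replicate 2. S1pr1, Gpr183, Engase, P2ry2, Fhl3 and Gata6 also failed without untreated replicate 2, and S1pr1, Engase and Gata6 without untreated replicate 3. The highest adjusted p reached in this way was 0.337, for Gata6, and the lowest was 0.0504, for Engase.

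Among markers of other cells, Klrk1 (0.94) rose after IFNg of 18 T and NK genes (median -0.20, adjusted p = 0.149), and not without IFNg replicate 1 or 2 (adjusted p = 0.108 to 0.146). The medians of the other lists were -0.18 for small macrophages, monocytes and dendritic cells, -0.32 for B cells, -0.20 for mast cells, -0.15 for neutrophils and eosinophils, -0.13 for mesothelial and stromal cells and -0.20 for erythroid cells and platelets, with no gene past the threshold. Leaving out both narrow arrays shrank them to -0.08, -0.22, -0.10, -0.07, -0.02 and -0.01 in the same order, and that of the T and NK genes to -0.06. None of these 7 lists passed in that fit (adjusted p = 0.121 or more). The B cell, mast cell and mesothelial lists passed as lower (adjusted p = 0.0135, 0.0315 and 0.0495) and did not with an estimated correlation (adjusted p = 0.629, 0.629 and 0.681), and the other 3 did not pass (0.0517 or more). Without untreated replicate 1 none of these 3 lists passed at the preset correlation either (adjusted p = 0.058 for B cells, 0.207 for mast cells and 0.622 for mesothelial cells). The B cell list also ended without untreated replicate 3 (0.0928), the mast cell list without IFNa replicate 4 (0.0676) and the mesothelial list without untreated replicate 2, IFNa replicate 1, 2 or 4 or IFNg replicate 2 (0.0515 or more). Of 23 immediate early genes Atf3 (1.71) and Egr2 (1.64) rose (median -0.14, adjusted p = 0.925), of 12 heat shock genes none passed (median 0.48, adjusted p = 3.22e-05, and 0.415 with an estimated correlation), and of 16 glucocorticoid targets Fkbp5 rose (2.58). That last list had a median of -0.10 and a mean of 0.27 (adjusted p = 0.35). Atf3 did not pass without IFNg replicate 1 or 2 (up to 0.14). Egr2 did not pass without any 1 of the untreated arrays, IFNa replicates 1, 2 or 3 or IFNg replicate 2 (up to 0.114).

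In all, 245 genes were higher and 22 lower after IFNg, and 217 and 13 of these changed at least 2-fold. Without the 2 arrays of narrow range the numbers were 358 and 145, and they included 239 of the 245 and all 22. Quantile normalization moved the share that were higher from 91.8% to 77.5% (276 higher and 80 lower), and it called 1 gene lower in each of the lists for receptor signalling, NF-kB targets and immediate early genes. Adjusted over the list alone, the numbers higher and lower were 11 and 0 for nucleic-acid sensing, 2 and 0 for receptor signalling, 4 and 1 for NF-kB targets, 4 and 2 for immediate early genes, 3 and 0 for glucocorticoid targets and 1 and 0 for small macrophages. Leaving out both narrow arrays moved the number higher from 3 to 6 for MHC class I, from 4 to 7 for feedback inhibitors, from 5 to 8 for nucleic-acid sensing, from 1 to 2 for receptor signalling and from 1 to 3 for glucocorticoid targets. It moved the number lower from 0 to 3 for immediate early genes, from 0 to 2 for NF-kB targets and from 0 to 1 each for nucleic-acid sensing, small macrophages and glucocorticoid targets. List medians in that fit were -0.09 for MHC class II, 0.04 for receptor signalling, 0.13 for nucleic-acid sensing, 0.29 for heat shock, -0.12 for alternative activation and -0.09 for cholesterol synthesis. Without untreated replicate 2, IFNg replicate 1 and IFNg replicate 2 the numbers higher were 138, 79 and 90 and the numbers lower 2, 1 and 3, and without IFNa replicate 4 the number lower was 44.

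**Figure D1:**
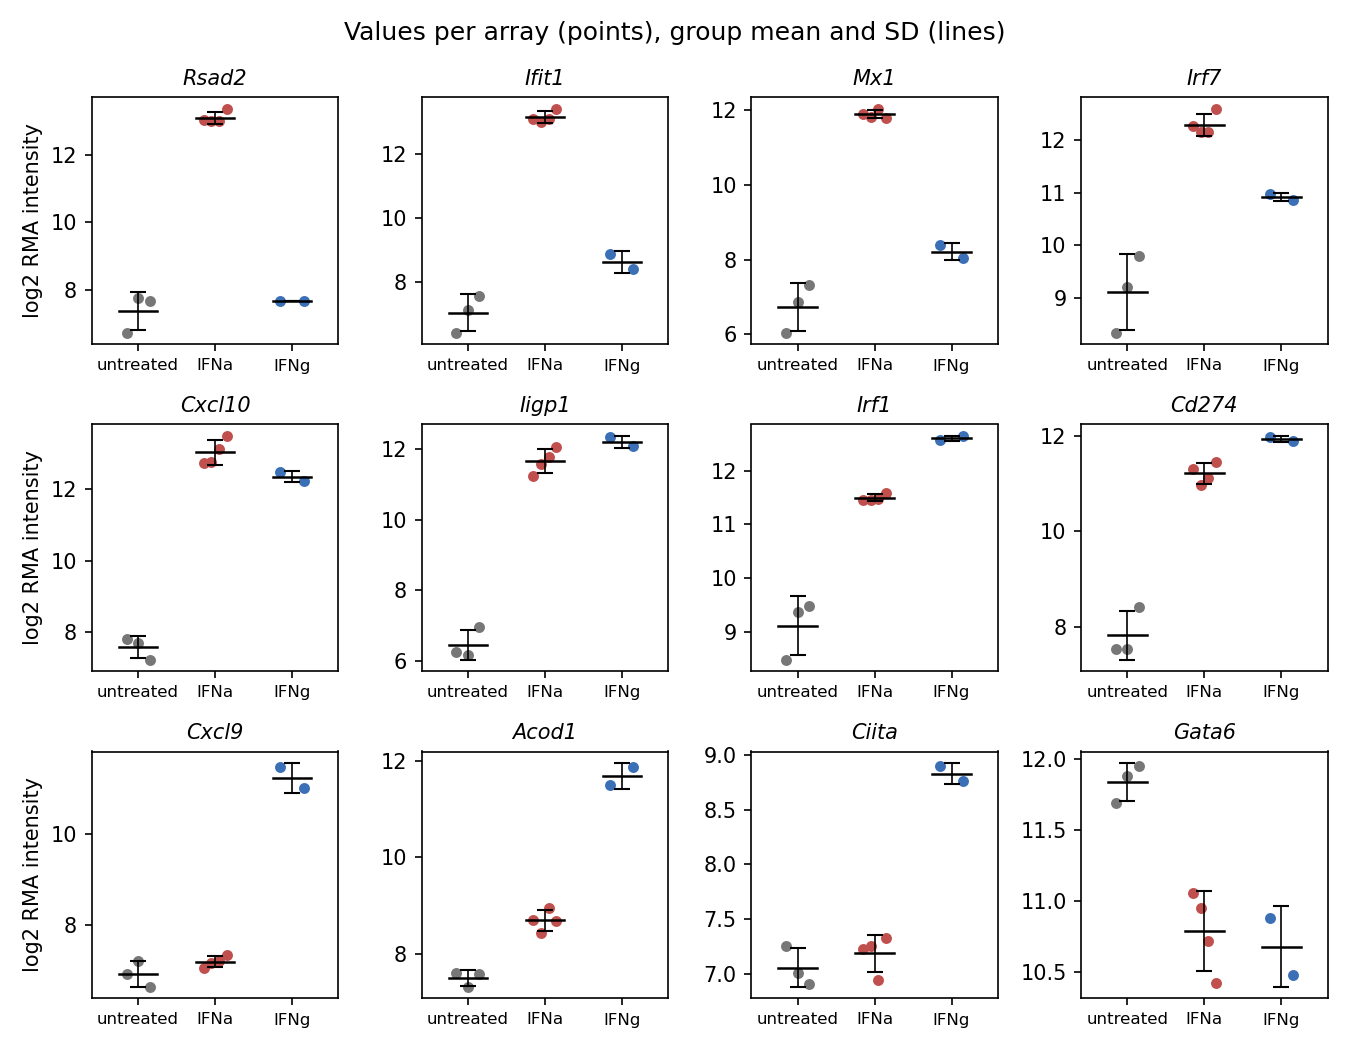
Log2 intensity of 12 genes in each array by group, with points for arrays and bars for the mean and SD (untreated n = 3, IFNa n = 4, IFNg n = 2). Ifit1 has a mean of 13.15 after IFNa and 8.62 after IFNg, against 7.03 in untreated cells.

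IFNa and IFNg were also compared with each other, which asked where the responses differ and used groups with the same sort label, though doses differed. The largest differences toward IFNa included those of antiviral genes. Rsad2 was 41.8-fold higher (log2 5.39 ± 0.26), Ifit3 40.6-fold (5.34 ± 0.22), Ifit2 36.9-fold (5.21 ± 0.18) and Mx1 12.7-fold (3.67 ± 0.29) in 4 IFNa against 2 IFNg mice. Cxcl9 was 16.8-fold higher after IFNg (IFNa minus IFNg -4.07 ± 0.19), Acod1 7.97-fold (-2.99 ± 0.18), Irf8, a transcription factor of macrophage identity, 4.22-fold (-2.08 ± 0.17) and Ciita 3.13-fold (-1.64 ± 0.15). Adjusted p-values of these 8 genes lay between 2.65e-06 and 7.81e-04. The arrays of the groups did not overlap, which the naming rule required of all but Ciita. Ifit3b (4.69), Ifit1 (4.53), Oasl1 (3.66), Mx2 (3.56), Ms4a4c (3.44) and Cmpk2 (3.27) completed the 10 largest toward IFNa. Toward IFNg they were completed by Gatm (-2.59), Fchsd2 (-2.29), Tnfaip2 (-2.29), Adgrf5 (-2.28), Hcar2 (-2.26), Cdc42ep2 (-2.24) and Dna2 (-2.05).

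Of 34 antiviral genes 17 were higher after IFNa and none after IFNg (list median 1.06, adjusted p = 0.0457 with an estimated correlation), and the number was 22 under quantile normalization and 15 under median centring. No other list passed both list tests in this comparison. Of 24 IFN-gamma-associated genes 9 were higher after IFNg (median -0.64, adjusted p = 0.0731 with an estimated correlation), and of 10 GTPases 1, Gbp11 (-1.82, adjusted p = 0.104 for the list with an estimated correlation). Trim14 (1.03) was the Schlafen or TRIM gene higher after IFNa (median 0.79, adjusted p = 0.103 with an estimated correlation). Among 26 genes of nucleic-acid sensing Ddx58 (1.62), Ifih1 (2.84-fold) and Tlr3 (1.04) were higher after IFNa and Sting1 (-1.89) after IFNg (median 0.21, adjusted p = 0.565 with an estimated correlation). Adjusted over the list alone, the numbers higher after IFNa and after IFNg were 28 and 0 of the antiviral genes, 1 and 15 of the IFN-gamma-associated genes, 0 and 2 of the GTPases, 8 and 0 of the Schlafen and TRIM genes and 8 and 2 for nucleic-acid sensing.

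Of 26 NF-kB targets Il6 (2.87) was higher after IFNa and Tnfaip2 and Icam1 (-2.01) after IFNg (median -0.04, and 0.02 under quantile normalization, adjusted p = 0.339). Of 19 cell death genes Tnfsf10 (1.69) and Daxx (adjusted p = 0.0336) were higher after IFNa and Bcl2l11 (3.99-fold), which encodes the death promoter BIM, and Casp12 (-1.54) after IFNg (median -0.03, and 0.08 under quantile normalization, adjusted p = 0.21). Usp18 (2.27) was the feedback inhibitor that differed, toward IFNa, whereas its list leaned toward IFNg (median -0.65). That list passed at the preset correlation (adjusted p = 0.0264, and 0.568 with an estimated correlation), though not without IFNa replicate 2 (0.0512). Of the feedback inhibitors 2 were higher after IFNa and 7 after IFNg when adjusted over the list alone, and the numbers were 5 and 5 for NF-kB targets and 3 and 5 for cell death genes. Socs1 (-1.57 ± 0.31, adjusted p = 0.0534), Irf1 (-1.11 ± 0.24, 0.0871), Irf7 (1.37 ± 0.32, 0.115), Cxcl10 (0.67 ± 0.24, 0.474) and Cd274 (-0.73 ± 0.25, 0.44) did not pass. Il4ra (-1.17) and Egr2 (-1.77) were higher after IFNg in the lists of alternative activation (median -0.02, adjusted p = 0.376, and no gene passed under quantile normalization) and immediate early genes (median -0.10, adjusted p = 0.0138, and 0.565 with an estimated correlation). The latter list did not pass without IFNg replicate 2 (0.288), and its median was -0.16 without both narrow arrays.

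Ciita and Cxcl9 were the genes that differed in the MHC class II list (median 0.06, mean -0.09, adjusted p = 0.71) and the chemokine list (median 0.03, mean -0.17, adjusted p = 0.839). No gene differed in the lists of MHC class I (median -0.07, and 0.01 under quantile normalization), receptor signalling (-0.01, and 0.09), complement (-0.08), cholesterol synthesis (-0.11) and cell cycle (-0.36), nor in those of heat shock (0.06, with a mean of -0.04) and glucocorticoid targets (0.04, with a mean of -0.09). The same held for the lists of large macrophages (0.03), small macrophages (0.04, with a mean of -0.01), B cells (0.32), T and NK cells (0.15), mast cells (0.15), neutrophils and eosinophils (0.08), mesothelial cells (0.18) and erythroid cells (0.09). Several of these lists passed at the preset correlation. Those for B cells (adjusted p = 1.93e-04), T and NK cells (0.00786), mesothelial cells (0.0105) and mast cells (0.0495) passed as higher after IFNa, and those for cell cycle (0.0089), cholesterol synthesis (0.0191) and MHC class I (0.0425) as higher after IFNg. With an estimated correlation the adjusted p of each list in this paragraph was 0.565 or more. At the preset correlation the T and NK list ended without IFNa replicate 4, the mesothelial list without IFNg replicate 2, and the mast cell list without IFNa replicate 1 or 4, IFNg replicate 1 or untreated replicate 3. The cell cycle list ended without IFNa replicate 4 or IFNg replicate 1, the cholesterol list without IFNa replicate 1 or 4 or IFNg replicate 2, and the MHC class I list without IFNa replicate 1 or IFNg replicate 1 (adjusted p = 0.0512 to 0.85 over these 6 lists). Without both narrow arrays the medians were 0.30 for B cells, 0.07 each for T and NK cells and mast cells, 0.02 for neutrophils and eosinophils, 0.09 for mesothelial cells, -0.02 for erythroid cells, -0.11 for MHC class I and 0.00 for cell cycle. In that fit the B cell and MHC class I lists passed at the preset correlation and the other 5 did not (0.0529 or more). With adjustment over the list alone, in the fit of all arrays, 1 MHC class I gene was higher after IFNa and 3 after IFNg, 1 receptor signalling gene was higher after IFNg, 1 T and NK gene after IFNa and 1 glucocorticoid target after each. The B cell genes Ms4a1 and Fcmr reached 9.05 and 8.89 in 1 IFNa array, replicate 2, against group means of 6.84 and 7.22 in untreated cells.

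In all, 87 genes were higher after IFNa and 106 after IFNg, and without the 2 arrays of narrow range 250 and 292, which included all 87 and all 106. Quantile normalization moved the share higher after IFNa from 45.1% to 58.0% (160 and 116 genes). Under it the numbers toward IFNa and IFNg were 6 and 1 for nucleic-acid sensing, 4 and 0 for Schlafen and TRIM genes, 2 and 3 for NF-kB targets and 2 and 1 for feedback inhibitors, and 1 gene was higher after IFNa in each of the lists for MHC class I, receptor signalling and glucocorticoid targets. Leaving out both narrow arrays moved the number toward IFNa from 3 to 10 for nucleic-acid sensing, from 1 to 8 for Schlafen and TRIM genes, from 1 to 4 for NF-kB targets and from 1 to 2 for feedback inhibitors, and from 0 to 1 each for MHC class I, receptor signalling, T and NK genes and glucocorticoid targets. The number toward IFNg moved from 0 to 6 for feedback inhibitors, from 2 to 4 each for NF-kB targets and cell death, and from 0 to 1 each for MHC class I, receptor signalling and glucocorticoid targets. Without IFNg replicate 1 the numbers were 21 and 21, without IFNg replicate 2 24 and 32, without IFNa replicate 1 53 and 68, and without IFNa replicate 3 49 and 63. Of the genes named, Gatm, Hcar2, Dna2, Usp18, Ifih1, Tlr3, Sting1, Ddx58, Il6, Daxx, Trim14 and Il4ra did not pass without either IFNg array, nor Fchsd2, Cdc42ep2 and Gbp11 without replicate 1, or Bcl2l11 and Tnfsf10 without replicate 2 (adjusted p = 0.0521 to 0.472). Egr2 did not pass without IFNa replicates 1, 2 or 3 (up to 0.0633). Dna2 and Tlr3 also ended without IFNa replicate 1, Tlr3 and Trim14 without IFNa replicate 3, Trim14 without IFNa replicate 2, and Daxx, Ddx58, Sting1 and Il4ra without IFNa replicates 1, 2 or 3 or untreated replicate 2. Ddx58 and Daxx also ended under median centring (0.0681 and 0.0637). Ddx58 further ended without IFNa replicate 4 and Il4ra without untreated replicate 3.

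**Figure D2:**
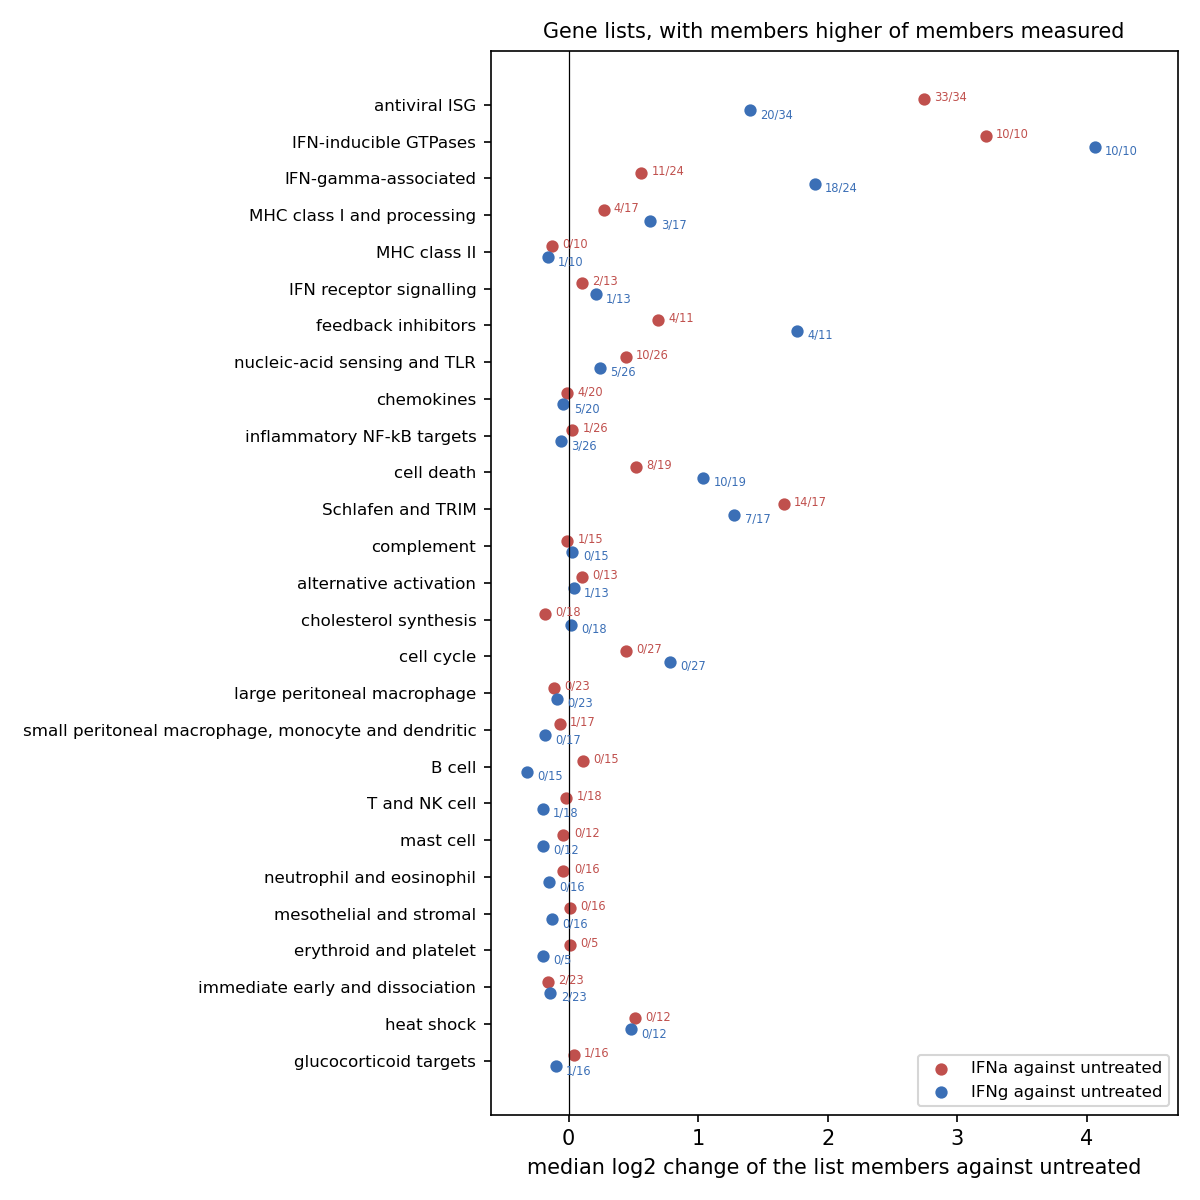
Median log2 change of each gene list against untreated after IFNa (n = 4) and IFNg (n = 2), with the number of members higher of those measured beside each point. The GTPase list has medians of 3.22 and 4.06, and several small medians lie near 0 and change sign with the scaling.

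The overlap of both responses was compared last, with the caveat that both used the same 3 untreated arrays. A total of 145 genes were higher after both cytokines and 19 lower after both, against 4.4 and 0.19 for lists drawn independently. Unchanged groups simulated 100 times against shared controls gave 0 shared genes in either direction, but in such groups the threshold lets almost no gene pass, so this count says nothing about a shared response. Part of the excess over independent lists may come from the shared controls. Cxcl10, Iigp1, BC023105, Cd274 and Ifi205 were higher after both cytokines, and Sox7, Htr2a, S1pr1, Engase, P2ry2 and Gata6 were lower after both. Without a vehicle group, neither the shared rises nor the shared falls can be assigned by this overlap to the cytokines rather than to injection or handling. A single gene passed in opposite directions, B430306N03Rik, which was named after its values were seen and stood at 0.63 after IFNa and -0.91 after IFNg. Across genes, which are not independent replicates, the log2 changes correlated at 0.63, and their covariance was 0.085. Simulated unchanged groups that share controls gave means of 0.48 and 0.020. Genes varied independently in these simulations, which leaves out variation that moves many genes of an array together. The gap therefore does not test a shared response. The share of genes with the same sign, 64.9%, was no higher than the simulated 65.9%.

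Of the 145 genes higher after both, 18 were higher after IFNa and 11 after IFNg in the direct comparison. Of 209 genes called higher after IFNa alone, 66 also differed directly, as did 60 of 100 called after IFNg alone, so a call in a single comparison often came without a tested difference. Without the 2 arrays of narrow range 183 genes were higher and 110 lower after both. The numbers were 89 and 2 without untreated replicate 2, 53 and 1 without IFNg replicate 1, and 57 and 3 without IFNg replicate 2, and the number lower was 12 without IFNa replicate 3 and 34 without IFNa replicate 4.

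**Figure D3:**
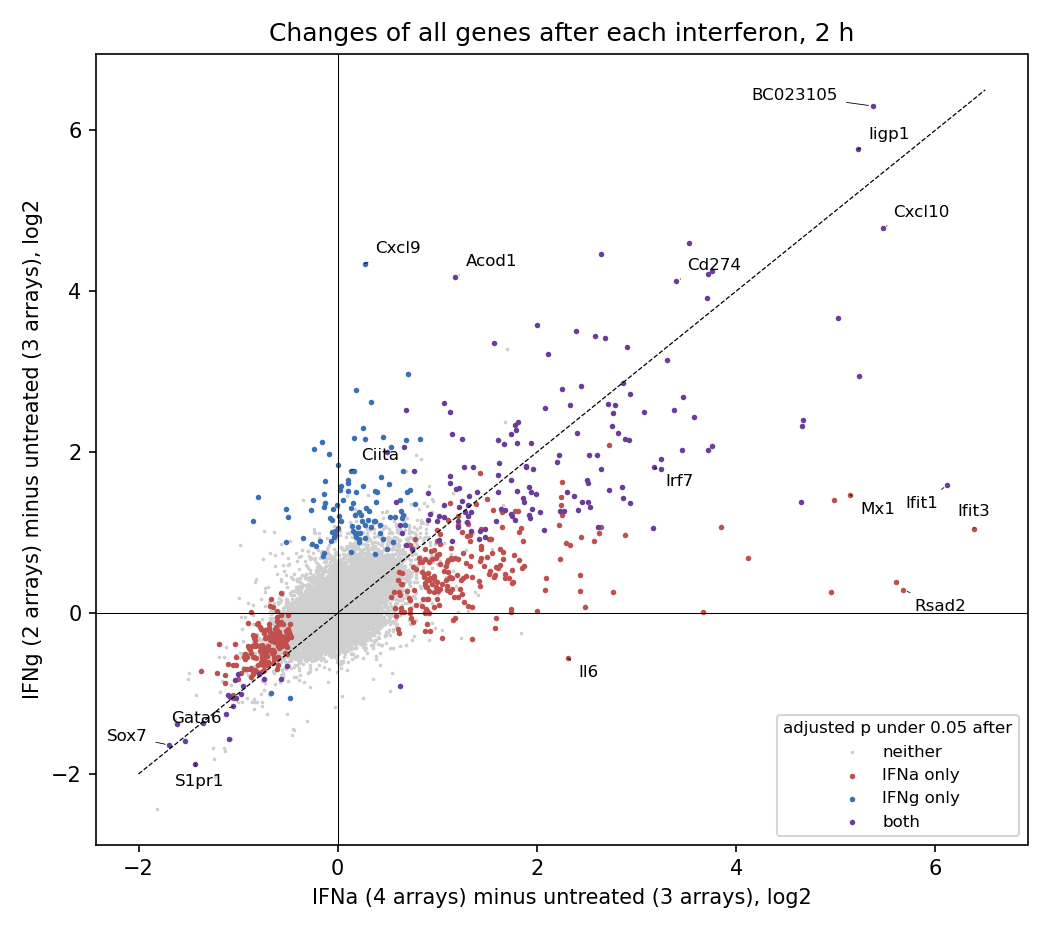
Log2 change of each gene after IFNa (horizontal) and after IFNg (vertical) against the same 3 untreated arrays, coloured by the comparison in which the adjusted p was under 0.05, with a dashed line of equal change. Cxcl9 (0.27 and 4.34) and Ifit3 (6.39 and 1.05) lie far from that line.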

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

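Of the tests in this part, the comparison of receptor genes with level-matched genes was chosen after the result was seen, and that with keratin-associated genes was fixed before.

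Of 116 values tested within the 4 IFNa arrays, 8 had 1 array far from the others, where chance gives about 1 in 20. Rsad2 stood at log2 13.35 in IFNa replicate 4, against 12.98 to 13.01 in the other IFNa arrays. H2-T24 stood at 11.45 in the same array, against 11.79 to 11.85. Ifi213 stood at 11.78 in IFNa replicate 1, against 11.23 to 11.30. Fkbp5 stood at 9.57 in IFNa replicate 1, against 9.29 to 9.33. Tnfaip2 stood at 9.75 in IFNa replicate 2, against 9.88 to 9.89. The median of the feedback inhibitors was 10.61 in IFNa replicate 4, against 9.64 to 9.78. The median of the heat shock genes was 9.53 in IFNa replicate 1, against 9.99 to 10.01. The mean correlation with the other IFNa arrays, across genes, was 0.95 for IFNa replicate 4, against 0.98 for the others.

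A signal also appeared in the 3497 probe sets outside the gene table, which carry several symbols or none. Of these, 63 were higher and 6 lower after IFNa, with a largest rise of log2 4.50, and 33 of the 63 carried several symbols. After IFNg 35 were higher and 0 lower by limma, with a largest rise of 5.26, and 13 of the 35 carried several symbols. In the direct comparison 1 was higher after IFNa and 2 after IFNg.

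Olfactory and vomeronasal receptor genes stood high in IFNa replicate 4: 99.1% of 1190 lay above the mean of the other IFNa arrays, by a median of log2 0.86, though 0 passed the threshold in any comparison. A narrowed range of the whole array would lift other dim genes as much, but 10000 lists matched on level rose by a median of 0.24 and at most 0.28, which left the receptor genes 0.61 above them. Those lists also argue against a signal added to all dim genes alike, whereas the test fixed in advance came out on the side of that explanation: 62 keratin-associated and cornified envelope genes rose by 0.67, and their excess over matched genes fell short of that of the receptors by 0.10 (interval -0.01 to 0.22). That interval, at 95%, came from resampling genes and not arrays. The weight given to these opposed results was settled after both were seen, so a source that reaches some gene families more than others, possibly genomic DNA, stays open. No biological explanation was tested.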

How the results depend on the processing

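The fits without the 2 arrays of narrow range and with array range as a covariate were chosen after seeing the data. No called gene that the naming rule chose changed direction under the alternatives run for it, and genes or comparisons of genes outside that rule were not run. Of the values of called genes under single alternatives 3006 stayed past the threshold and 239 did not. Of values of uncalled genes 290 passed, 134 of them in the fit with array weights, and 51 changed sign without passing. The totals for called genes include that fit as well, though the estimation of its weights did not converge. For called lists 568 stayed past it, 133 did not and in 3 the list test turned. List tests were not run under quantile normalization, median centring, robust variances or array weights. Nor were they run in the fit of only the groups compared, with blocks by description number or with every probe set. The totals for lists therefore leave those alternatives out. Dim signal close to background limits what can be seen, and the arrays hold no separate measure of it. Except where fewer arrays, fewer genes or a stricter threshold account for it, the cause was not tested.

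In IFNa against untreated (354 higher, 169 lower), the number higher was 933 with the covariate, and the number lower was 887 with it, 638 without the narrow arrays, 421 under quantile normalization, 105 under median centring, 100 with an intensity trend, 74 with only the 2 groups, 26 at 2-fold and 31 at an adjusted p under 0.01. In IFNg against untreated (245 and 22), the number higher was 112 with only the 2 groups and 128 at 0.01, and the number lower was 116 with the covariate, 145 without the narrow arrays, 80 under quantile normalization, 7 with only the 2 groups, 13 at 2-fold and 3 at 0.01. In the direct comparison (87 higher after IFNa, 106 after IFNg), the former was 160 under quantile normalization and the numbers were 250 and 292 without the narrow arrays, 237 and 160 with the covariate and 42 and 48 at 0.01. Shared genes (145 higher, 19 lower) numbered 79 and 2 at 0.01, and 70 and 5 with only the 2 groups compared, and the number lower was 110 without the narrow arrays, 94 with the covariate, 59 under quantile normalization and 11 at 2-fold.

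Array weights gave 3414 higher and 5930 lower after IFNa, 3854 and 6046 after IFNg, 603 and 1037 in the direct comparison, and 2534 and 4251 shared. The estimated weights ran from 0.09 to 140.64, with the highest on untreated replicate 2, so these counts rest on that array, and the estimation of the weights stopped before it converged. Replicate numbers as a block gave, by title, 587 higher after IFNa, 589 higher and 110 lower after IFNg, and 293 higher and 61 lower after both. By description they gave 726 higher after IFNa than in untreated cells and, in the direct comparison, 56 higher after IFNg. Whether the numbers pair the arrays could not be settled. In deviations from group means, 3 of 7 pairs with the same title number correlated above 0.1, with a range of -0.21 to 0.60. The deviations of the 2 IFNg arrays mirror each other, so pairs with them are not independent. The highest correlation between groups, 0.61, joined arrays of unlike number, untreated replicate 1 and IFNa replicate 4.

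Leaving out 1 array at a time gave 261 to 444 higher and 27 to 255 lower after IFNa, 79 to 363 and 1 to 44 after IFNg, 21 to 130 and 21 to 146 in the direct comparison, and 53 to 213 and 1 to 34 shared. A lone IFNg array was assumed to vary like the other groups. The lowest came without untreated replicate 2 for IFNa and without IFNg replicate 1 for the rest. The highest came without untreated replicate 3 for higher counts after each cytokine and shared, untreated replicate 1 for lower counts after IFNa and the direct ones, and IFNa replicate 4 for lower counts after IFNg and shared.

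Lists past the threshold numbered 14, 16 and 14 in the 3 comparisons, and 4, 7 and 1 with an estimated correlation. In the direct comparison they numbered 8 and 6 without the dimmest 30% and 50% of genes, 9 without the narrow arrays and 6 with the covariate. Leaving out 1 array gave 11 to 14, 12 to 16 and 10 to 14. List tests that turned were those of the mast cell list after IFNg (median -0.20, and 0.37 without the dimmest 50%) and, in the direct comparison, the cholesterol list (-0.11, and 0.02 with the covariate), the cell cycle list (-0.36, and 0.18 with the covariate) and the heat shock list (0.06, with a list test toward IFNg), whose medians ran from -0.36 without IFNg replicate 2 to 0.27 without IFNg replicate 1. List medians changed sign more often, 38 of 81 under at least 1 alternative, 9 of them in lists past the threshold, and none of the 38 exceeded 0.36 in size with all arrays and settings as reported.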

Other observations

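Apart from the split count, each test in this part was chosen after its result was seen. The genes in the next paragraphs were likewise chosen after their values were seen.

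Il15, which sustains NK and memory T cells, rose by log2 2.51 ± 0.20 after IFNa (n = 4) and 1.38 ± 0.24 after IFNg (n = 2), and Il15ra, which presents it, by 1.87 ± 0.16 and 1.38 ± 0.20. Cd69, an early activation marker, rose by 3.58 ± 0.25 and 2.44 ± 0.29. Nampt, which makes a precursor of NAD, rose by 2.25 ± 0.28 and 2.78 ± 0.34. None of these 4 genes passed in the direct comparison (adjusted p = 0.0542, 0.533, 0.134 and 0.802). Il18 rose after IFNa (2.24 ± 0.28) and stood at 1.34 ± 0.34 after IFNg (adjusted p = 0.134). Neighbours of Ifi213 and Ifi208 in the family of DNA-binding PYHIN proteins also rose after IFNa, Ifi214 by 3.85 ± 0.23 and Ifi209 by 3.76 ± 0.29, and Ifi214 was higher after IFNa than after IFNg (2.79 ± 0.26, adjusted p = 8.27e-04).

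Some genes differed between the cytokines outside the lists. Phf11a, Phf11c and Phf11d were higher after IFNa than after IFNg by 1.07, 1.56 and 1.19, as were the histone methyltransferase gene Setdb2 (1.43 ± 0.22, adjusted p = 0.0167) and Gch1 (1.16 ± 0.18, adjusted p = 0.0163), whose product starts tetrahydrobiopterin synthesis. Toward IFNg lay Csf2rb, the shared receptor chain for GM-CSF, IL-3 and IL-5 (-1.35 ± 0.15, adjusted p = 0.00281), the aryl hydrocarbon receptor gene Ahr (-1.53 ± 0.24, adjusted p = 0.0167) and the glucose transporter gene Slc2a1 (-1.13 ± 0.18, adjusted p = 0.0175). Pfkfb3, a driver of glycolysis, rose by 2.22 ± 0.27 after IFNg and 1.15 ± 0.23 after IFNa, and did not pass directly (adjusted p = 0.128). These genes were not run through the alternatives.

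A set of 19 genes, Gata6 among them, was lower after both cytokines. The label of the untreated sort lacks ICAM2, though the description of the series gives 1 sort for all. Small macrophages, monocytes or dendritic cells without that marker would bring their own transcripts, but their list had medians of -0.07 after IFNa (interval -0.19 to 0.10) and -0.18 after IFNg (-0.26 to -0.02), far from the -0.5 or lower set as the bound, and 0 members were lower at an unadjusted p under 0.05 by limma. Both intervals, at 95%, came from resampling the genes of the list and not the mice, so they leave out the spread between arrays. The B cell, mast cell and mesothelial lists passed as lower after IFNg (medians -0.32, -0.20 and -0.13), though not with an estimated correlation or without the narrow arrays, and their medians after IFNa were 0.11, -0.04 and 0.01. Other cells in the untreated sort are therefore not excluded. Injection, handling or processing that differed for the untreated mice and a shared effect of both cytokines cannot be told apart, because no vehicle group exists and 0 of the 19 genes differed between the cytokines at an unadjusted p under 0.05. The set is fragile: without IFNg replicate 1 it held 1 gene, without IFNg replicate 2 3 genes, without untreated replicate 2 2 genes, without IFNa replicate 3 12 genes and without IFNa replicate 4 34 genes.

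Cell cycle genes varied together within groups. The median of 27 genes was log2 8.69, 9.24, 9.69 and 7.72 in the IFNa arrays, 7.93, 8.08 and 9.10 in the untreated and 9.44 and 9.06 in the IFNg arrays, and over the IFNa arrays Mki67 ranged over 2.16, Top2a over 2.69 and Bub1 over 2.82. A narrow range that acts alike on genes of one level is argued against. Without the 2 narrow arrays the spread within groups was 0.45, where 99% of 10000 level-matched lists stayed under 0.11 and the highest reached 0.14. The list median still rose with the quartile ratio in IFNa replicates 1 to 3, at log2 2.70, 2.79 and 2.91. It did so in untreated replicates 2 and 3, at 2.68 and 3.03, but not in the IFNg arrays, at 2.93 and 2.99. A link of these genes with array range therefore stays open. The list median ranged over 1.97 within the IFNa arrays, and over 1.01 without IFNa replicate 4, while group means differed by at most 0.88. These ranges do not test an effect of the cytokines, since the arrays of a group had the same treatment, and such an effect stays open. Differences between mice or sorts in the share of dividing cells may account for the variation within groups and were not tested.

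All 35 splits of the 4 IFNa and 3 untreated arrays into groups of 4 and 3 were fitted. The real split called 523 genes and 1 other split called 1071, so 2 of 35 gave as many and chance cannot be excluded by this count. That other split placed IFNa replicate 4 and untreated replicate 1, the 2 narrow arrays, on 1 side with untreated replicate 2, which points to a structure of the samples. That split also followed the order of array range. The quartile ratio was log2 2.16, 2.27 and 2.68 in these 3 arrays and 2.70 to 3.03 in the 4 on the other side. The gap at the cut was small, from 2.68 in untreated replicate 2 to 2.70 in IFNa replicate 1. The cell cycle medians lay at 7.72 to 8.08 on the former side and 8.69 to 9.69 on the latter, and no test tied the calls to either measure. It shared 0 genes with the real split and called 0 of 34 antiviral genes, against 33. Its largest difference was 1.85, against 6.39. The second highest other split called 1 gene, and without the narrow arrays the real comparison gave 468 genes higher and 638 lower.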
